A study of Ichthyophthirius multifiliis with 14 samples.

How the data were processed

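Total RNA was extracted with Trizol and made into libraries with an Illumina mRNA-seq kit, per the labels' protocols. HISAT and StringTie are named in the submitters' processing notes, without version. The genome build and the strand setting are not given in the sources used here. The authors deposited a gene table and an isoform table, each of which gives FPKM (fragments per kilobase of transcript, scaled to library size) and whole-number counts side by side for 14 libraries, per the file headers. Each table as used here held 99 rows. All 99 genes matched the reference annotation (assembly JCVI-IMG1-V.1) by locus tag, with identical start and end. The tables share 36 genes with identical values, and the isoform table adds 48 loci with 63 transcripts.

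Because the tables hold part of the transcriptome, their column sums are not library sizes. Library totals were recovered as the median of count / (FPKM × length) over the 40 transcripts with at least 50 counts in every library. The values of one library spread by at most 0.259% over those transcripts. Totals ran from 50787300 to 65698100 fragments.

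Groups were taken from titles and descriptions. The series text lists 4 controls, and the library titled C5 was kept out of the main fit. Libraries of one group differed by more than sampling noise (chi-square per degree of freedom of 5.25 or more in every pair), so none was treated as a repeat deposit of another, and each counted as 1 replicate. This does not show separate samples, since repeated preparations of 1 sample would also exceed that noise. The lowest 3 values were those among control replicates 1, 2 and 3 (5.25, 6.18 and 7.42, against 15.3 to 15.7 with control replicate 4), whose descriptions share a stem.

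The test chosen before the data were examined was limma on log2(FPKM + 1) for genes with a mean FPKM of 1 or more. The tables turned out to hold counts as well, so the main test became edgeR's quasi-likelihood test on the deposited counts, and limma became an alternative. The recovered totals served as library sizes with no further factor, which keeps the scaling of the authors' FPKM. This choice was settled after the counts of genes under other scalings and tools had been seen. The scaling of FPKM was also the one assumed beforehand, but TMM, RLE, a common table total and median centring each leave no rise past the threshold in the comparisons with control. Genes were kept with filterByExpr (minimum count 10), all 13 listed libraries entered one fit, tests were two-sided, and p-values were adjusted over the genes tested (Benjamini-Hochberg) with a threshold of 0.05. The standard error is the log2 fold change divided by the root of F. A group without counts was given a floor of 3 counts over the group. The limma test written beforehand called 16, 0, 19, 0 and 0 of 32 genes in the comparisons of 0.5 h, 1.5 mg/L 1 h, 3.5 mg/L, time and dose. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.

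Genes are named by a rule fixed beforehand: in each comparison with control, up to 10 risers and 10 fallers past the threshold with non-overlapping groups and an informative product name (5 and 5 between magnolol groups), the 10 genes with the smallest p where fewer than 10 qualified, and up to 4 members per list by p at 3.5 mg/L. Only genes with values that bear on a comparison are quoted. The loci outside the gene table, IMG5_205740 among them, were named after their values were seen. Gene lists were fixed by product name, and a set test (camera with a preset correlation of 0.01, fry beside it) was run for lists with 5 or more genes tested, which only the metalloproteases reached. The E(z), ATPase, calcium channel and rab11 lists hold 1 or 2 tested genes.

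The pipeline was tested on data simulated for the comparison of 3.5 mg/L with control, from the 76 genes' means, totals and dispersions, with 20 genes changed in each of 20 simulations. edgeR called 64.3% of 4-fold and 12.1% of 2-fold changes and 0.919% of unchanged genes. DESeq2 called 71.9%, 21.7% and 2.21%. The test chosen beforehand, limma, called more of the changes than edgeR, at 81.0%, 25.8% and 0.633%. It was run only on genes with a mean FPKM of 1 or more (121, 97 and 474 against 199, 198 and 1088 with edgeR). These rates are therefore not over the same genes. In these simulations changes near 2-fold were thus mostly missed at this depth and number of libraries. The simulated genes varied separately, with no shift of the whole table and no division of the libraries, so these rates need not hold for the real data. There, control replicates 1, 2 and 3 set against the other libraries of the 3.5 mg/L comparison gave 23 calls.

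Alternatives were other pseudocounts, filters, scalings, spread estimates and library choices, the isoform table, a replicate block, and each library left out in turn. Those chosen after seeing the data were DESeq2, the filter at a mean of 1 FPKM, TMM and RLE factors, fits without the libraries that lay apart or with 1 library of a group, camera with a correlation estimated from the data, the added loci, control replicates 1, 2 and 3 summed into 1 sample, and a replicate block with only the groups of the time comparison. Over all comparisons, controls included, the replicate numbers did not clearly pair the libraries: 9 of 18 same-numbered pairs correlated above 0.1, with r from -0.31 to 0.35 (mean 0.0734, against -0.0276 for other pairs). In the comparison of 1 h with 0.5 h all 3 same-numbered pairs did (0.154 to 0.191), and a block by number gave 0 genes there, as without it, in the full fit and with only the groups compared (10 and 6 with an unadjusted p under 0.05, edgeR, against 5). For the doses at 1 h the same-numbered pairs had r of 0.347, -0.00878 and 0.100. Between 0.5 h at 1.5 mg/L and 1 h at 3.5 mg/L they had 0.279, 0.0325 and 0.0473. Pairing by number among the magnolol groups thus stays open, and the dose comparison was not refitted with a block and only its own groups. Other splits of the libraries were refitted in full, and 1000 simulations, with each gene drawn separately, gave the values expected from shared controls.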

Results

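Gene expression was measured by RNA sequencing in Ichthyophthirius multifiliis, the ciliate that causes white spot disease in freshwater fish, while it was on the skin of goldfish. The parasites, of the G5 strain, were left untreated or exposed to magnolol, a phenolic compound of magnolia bark. Water was kept at 22 to 23 °C. The series held 14 libraries. Of these, 4 were untreated controls. The descriptions of control replicates 1, 2 and 3 share one stem and number them, while control replicate 4 and C5 carry stems of their own, so these 3 libraries may be repeats of 1 control sample, and n = 4 then overstates the controls. The lower dose, 1.5 mg/L, was applied during 0.5 h in 3 libraries and during 1 h in another 3, and the higher dose, 3.5 mg/L, during 1 h in 3. Another library, titled C5, is not among the controls that the series text lists, and it entered no main comparison. Nothing in the labels says whether replicates came from separate fish or parasite cultures, so the p-values measure the spread between these libraries, which may be technical.

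The gene table analysed here held 99 genes, 1.21% of the 8213 genes of the reference annotation, and the rest were not analysed here. These are weakly expressed genes, with a highest mean of 5.01 FPKM (fragments per kilobase of transcript, scaled to library size). The library totals behind the FPKM values ran from 50787300 fragments in control replicate 2 to 65698100 in 0.5 h replicate 2. The 99 genes together drew between 3830 and 10578 counts per library. At these totals 3 counts in a gene of 1 kb correspond to 0.0457 to 0.0591 FPKM. Intervals and floors cover counting error only. After the filter on low counts, 76 genes were tested. Product names are those of the deposited table. Control replicates 1, 2 and 3 and replicates 1 and 3 of 1.5 mg/L 1 h lay apart from the other 9 libraries. This was judged by correlations, across genes, of deviations from the mean of the 14 libraries. Every comparison below with the controls carries this division.

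The first question was how untreated and exposed parasites differed after 1 h at 3.5 mg/L, the higher dose. The casein kinase I-like gene IMG5_205360, of a family of serine/threonine kinases, rose from 0.772 ± 0.318 FPKM (SD, n = 4) to 2.67 ± 0.400 (n = 3), a 3.43-fold change (log2 1.78, SE 0.45, adjusted p = 0.0171, edgeR's quasi-likelihood test). IMG5_205370, named after the cation-transporting ATPase 13A2, rose from 0.343 ± 0.30 to 1.90 ± 0.489 FPKM (5.41-fold, log2 2.43, SE 0.72; 3.21 without control replicate 4, the call being lost in 4 of 13 fits with 1 library left out). The synaptojanin-1-like gene IMG5_201630, of a family of inositol phosphatases that act in vesicle recycling, rose from 0.398 ± 0.252 to 1.59 ± 0.447 FPKM (3.99-fold, SE 0.55). IMG5_201460, named after the voltage-activated calcium channel Cav1, rose from 0.219 ± 0.159 to 0.745 ± 0.138 FPKM (3.37-fold, log2 1.75, SE 0.49; 2.37 without control replicate 4). In each of these genes all 3 exposed libraries lay above all 4 controls, which the rule for naming them required, so this adds no support.

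Another 3 genes with informative names rose at 3.5 mg/L by 2 to 3 fold. IMG5_205160, named after the histone methyltransferase E(z), which modifies chromatin in repressed genes, went from 0.471 ± 0.157 to 1.41 ± 0.625 FPKM (2.97-fold, SE 0.43). IMG5_201230, similar to the microtubule-associated kinase MAST4, went from 1.49 ± 0.470 to 3.62 ± 0.531 FPKM (2.42-fold, SE 0.34). IMG5_201370, similar to the cilia- and flagella-associated protein 47, went from 0.940 ± 0.284 to 1.92 ± 0.240 FPKM (2.05-fold, SE 0.29). IMG5_205370 and IMG5_205360 are neighbours on scaffold NW_004085870.1, at 3187 to 4771 and 1601 to 2799, on opposite strands. Whether the counting used strand is not given in the sources used here, so reads from their facing ends cannot be told apart. IMG5_201460 (113385 to 118803), IMG5_201370 (75789 to 85253), IMG5_201630 (190906 to 193321) and IMG5_201230 (398 to 2127) lie on scaffold NW_004085885.1 of assembly JCVI-IMG1-V.1.

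**Figure D1:**
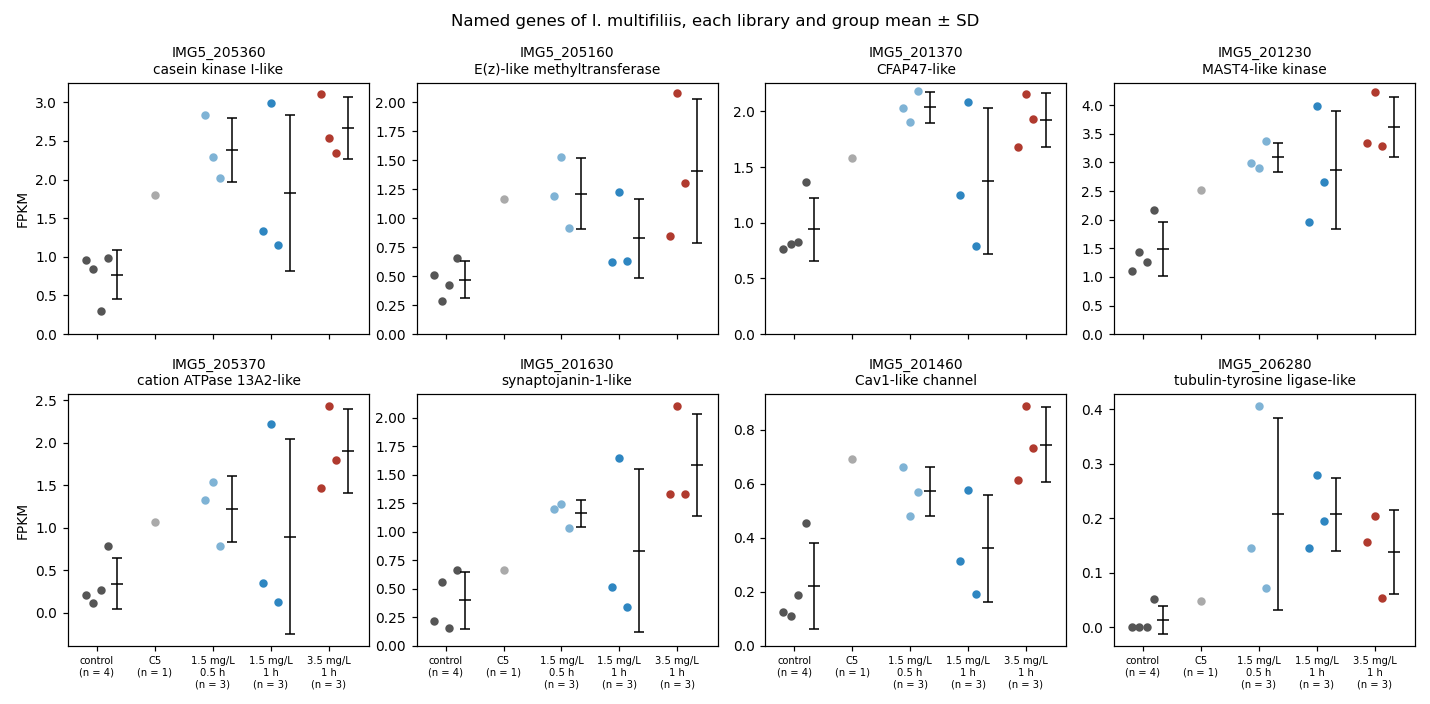
FPKM (vertical axes, linear) of 8 named genes in each library (points), with the mean ± SD of each group of 3 or 4 libraries (black bars); C5 is a single library outside the main comparisons. For IMG5_205360 the 3 libraries of 3.5 mg/L averaged 2.67 FPKM against 0.772 in the controls, and the 1.5 mg/L 1 h libraries spread widely (1.83 ± 1.01).

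In all, 14 genes rose and 1 fell at 3.5 mg/L, and 33 of 76 had an unadjusted p under 0.05. Of the risers, 7 have no informative product name. Among them IMG5_202730 went from 1.25 ± 0.289 to 3.25 ± 0.344 FPKM (2.59-fold) and IMG5_201330 from 0.139 ± 0.0870 to 0.612 ± 0.0582 (4.22-fold). IMG5_201900 had no count in any control and 82 counts in the exposed group, 1 library of which was at 0 FPKM. This makes it at least 36.4-fold higher against a floor of 3 counts over the group, and the 95% exact counting interval of the ratio starts at 29.0. The fitted log2 of 7.79, which depends on the prior count, was 6.79 without 3.5 mg/L replicate 2 (adjusted p = 0.0770, edgeR) and 8.38 without replicate 3. The gene that fell, IMG5_205990, with no product name, held 91 counts in the controls (1.44 ± 0.545 FPKM) and 0 in the exposed group, at least 22.8-fold lower against the same floor, with a counting interval of the ratio up to 0.0552. Groups did not overlap in 35 genes upward and 2 downward, where chance gives 2.86% of genes in each direction. Such a share, here and below, is an average over groupings. Genes that shift together can pass it together, so the count does not test exposure. The untreated library C5 lay above all 4 controls in 36 of 76 genes, where chance gives 20%.

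Of the 24 gene lists fixed before the data were examined, 16 had no member in the gene table. These covered chaperones, redox defence, respiration, glycolysis, ribosomal proteins, translation, ribosome biogenesis, splicing, the proteasome, papain-family proteases, multidrug transporters, lipid metabolism, immobilization antigens, xenobiotic metabolism, amino acid metabolism and host fish cells. Members were found by the wording of product names, so an empty list does not show that no such gene was measured. The genes named hisS (IMG5_201260) and MFS-type transporter-like (IMG5_206260), for example, matched no list. At 3.5 mg/L, 1 of 3 tested cilia and microtubule genes (IMG5_201370), 1 of 3 genes of the fixed protein kinase list (IMG5_201230), 1 of 2 ion channel and cyclic nucleotide genes (IMG5_201460), the only P-type ATPase (IMG5_205370) and the only chromatin and replication gene (IMG5_205160) rose. The cilia list gave 2 when adjusted over the list alone, the other 4 lists 1 each. The rab11-like gene IMG5_203660 of vesicle traffic had 1.70 (log2, SE 0.85, adjusted p = 0.124 with edgeR), and the calmodulin-dependent phosphodiesterase IMG5_203050, the only calcium binding gene, 2.03 (SE 1.06, adjusted p = 0.132; 3.08 without control replicate 1); both lists gave 0 when adjusted over the list alone. The kinase IMG5_203360 had 1.32 (SE 0.60); it was 2.21 without control replicate 4, and it passed in 7 of 22 other settings and in 2 of 13 fits with 1 library left out. The names of the casein kinase I genes fall outside the pattern of the kinase list: IMG5_205360 rose, as given above, and IMG5_203180 had -0.92 (adjusted p = 0.285, edgeR).

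The leishmanolysin-like metalloproteases, surface peptidases named after the major surface protease of Leishmania, gave no call at 3.5 mg/L as fitted here. None of the 5 tested members passed, over all genes or adjusted over the list alone (edgeR). IMG5_203530 had an unadjusted p of 0.0161 (log2 1.43, SE 0.54, adjusted p = 0.0623 with edgeR). It passed in 10 of 22 other settings and in 4 of 13 fits with 1 library left out, with log2 from 0.92 without 3.5 mg/L replicate 1 to 2.13 without control replicate 4. IMG5_206010 measured 1.67 ± 0.400 FPKM in controls and 1.50 ± 0.250 at 3.5 mg/L (log2 -0.15, which turned to 0.068 without the 5 libraries that lay apart), and IMG5_206040 1.58 ± 0.299 and 1.26 ± 0.302 (log2 -0.32, and 0.15 without those 5). Both passed as falls with quantile normalization (-0.60 and -0.73, adjusted p = 0.0210 with limma), and IMG5_206010 with RLE factors (-1.21, adjusted p = 0.0252 with edgeR). No difference of the list from the other genes was found (camera p = 0.274, direction down, and p = 0.481 with an estimated correlation), but without the 5 libraries that lay apart it passed downward (camera p = 0.00413, and 0.0292 with an estimated correlation). In that fit the controls were control replicate 4 and C5, and 7 members were tested. Downward there means relative to the other genes, since IMG5_206010 and IMG5_206040 had changes above 0, as given above. With all 13 libraries, the list's median log2 change was 0.42 and its mean 0.41. Its members are near copies by name, so reads may be split between them.

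The rises at 3.5 mg/L lay on a shift of the whole table. The median log2 change of the 76 genes was 1.01, and relative to that median IMG5_205370 stood at 1.43, IMG5_201630 at 0.99, IMG5_205360 at 0.77, IMG5_201460 at 0.74, IMG5_205160 at 0.56, IMG5_201230 at 0.27 and IMG5_201370 at 0.03. With TMM factors, which remove most of such a shift, 0 genes rose and 1 fell (IMG5_205990), against 14 and 1, so that each rise named above lost its call. The TMM factors came from the 76 genes alone, and the gene table holds at most 0.0174% of a library's total. They assume that most of these genes are unchanged, so they cannot tell a scaling error from a rise shared by these genes. In the genes listed next both the changes and their errors became smaller. An adjusted p also depends on the p of the other genes, so why the calls ended was not tested. IMG5_205370 had 1.64 (SE 0.56) with TMM factors and 1.97 (SE 0.62) with each library centred on its median, IMG5_201630 1.14 (SE 0.41) and 1.50 (SE 0.46), IMG5_205360 0.93 (SE 0.36) and 1.29 (SE 0.38), IMG5_201460 0.95 (SE 0.36) and 1.29 (SE 0.41), IMG5_205160 0.69 (SE 0.33) and 1.07 (SE 0.36), IMG5_201230 0.42 (SE 0.25) and 0.79 (SE 0.27), and IMG5_201370 0.19 (SE 0.16) and 0.55 (SE 0.20). Their adjusted p ran from 0.126 to 0.465 with TMM factors and from 0.0578 to 0.0855 with centring (edgeR). In IMG5_201370, which stood at 0.03 relative to the median, centring left 0.55, so it removed only part of the shift. The choice to leave such factors out was made after these counts had been seen. With control replicates 1, 2 and 3 summed into 1 sample, 0 of 83 genes passed (edgeR; 14 with an unadjusted p under 0.05), so the calls depend on counting these 3 libraries as separate. In contrast, limma on log2(FPKM + 1), the test chosen beforehand for FPKM values, called 19 of 32 genes. Left out in turn, control replicates 1, 2, 3 and 4 gave 5, 5, 0 and 27 genes, replicates 2 and 3 of 1.5 mg/L 1 h gave 29 and 24, and 0 genes passed without 3.5 mg/L replicate 2. Control replicate 4 lay above the other controls in IMG5_201370 (1.36 FPKM against 0.766 to 0.824) and IMG5_203360 (2.38 against 0.325 to 0.666).

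The second comparison asked what was seen after the shortest exposure, 0.5 h at 1.5 mg/L. IMG5_205360 rose to 2.39 ± 0.417 FPKM (n = 3; 3.08-fold, log2 1.62, SE 0.45, adjusted p = 0.0360, edgeR), IMG5_205160 to 1.21 ± 0.306 (2.56-fold, SE 0.43), IMG5_201370 to 2.04 ± 0.138 (2.17-fold, SE 0.29) and IMG5_201230 to 3.09 ± 0.252 (2.07-fold, SE 0.34). IMG5_206280, similar to tubulin-tyrosine ligases, which add a tyrosine to the end of tubulin, also rose, from 4 counts in the controls to 49 (0.0129 ± 0.0257 to 0.208 ± 0.176 FPKM). That is a ratio of 15.2 with a 95% exact binomial counting interval of 5.59 to 58.2, and the adjusted p was 0.0488. Its log2 change of 3.77 was 2.87 without 0.5 h replicate 2 and 6.96 without control replicate 4, which held all 4 control counts, and its call was lost in 10 of 13 fits with 1 library left out. Unnamed genes that rose were IMG5_201330 (4.43-fold), IMG5_204430 (3.01-fold), IMG5_200840 (2.49-fold) and IMG5_202730 (2.25-fold). IMG5_205990 fell from 91 counts to 2, a ratio of 0.0273 with an interval of 0.00326 to 0.102. It lost its call in 9 of 13 fits with 1 library left out, among them that without 0.5 h replicate 2 (fitted log2 -7.54 against -4.95, adjusted p = 0.0687, edgeR).

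Altogether 9 genes rose and 1 fell after 0.5 h, and 30 had an unadjusted p under 0.05. The groups did not overlap in 35 genes upward and 1 downward. Of the fixed lists, 2 of 3 cilia and microtubule genes, 1 of 3 genes of the kinase list and the only chromatin gene rose, and the same numbers passed when adjusted over the list alone. The ATPase IMG5_205370 (log2 1.79, SE 0.71) and the channel IMG5_201460 (1.37, SE 0.48) did not pass over all genes, and each gave 1 call when adjusted over its list alone. The rab11-like and phosphodiesterase lists gave 0 both ways. Outside the kinase list, IMG5_203180 had -0.96 (adjusted p = 0.231, edgeR). None of the 5 leishmanolysin-like genes passed either way (camera p = 0.819, down; 0.882 with an estimated correlation), with a list median of 1.39 and a mean of 0.86. The median over all 76 genes was 1.08, and relative to it IMG5_205360 stood at 0.54, IMG5_205160 at 0.27, IMG5_201370 at 0.03 and IMG5_201230 at -0.03.

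With TMM factors 0 genes rose and 1 fell at 0.5 h, against 9 and 1, and limma called 16 of 32 genes. With control replicates 1, 2 and 3 summed into 1 sample 0 of 83 passed (edgeR; 10 with an unadjusted p under 0.05). The count was 1, 0, 0 and 26 without control replicate 1, 2, 3 or 4, and 0 without any one of the 3 exposed libraries. It was 4, 27 and 23 without replicate 1, 2 or 3 of the 1.5 mg/L 1 h group, which shares the estimate of spread, and 3 without replicate 2 or replicate 3 of 3.5 mg/L. All 9 rises lost their call with TMM factors, as at 3.5 mg/L. With TMM factors and with centring IMG5_206280 had 3.04 (SE 1.20) and 3.34 (SE 1.20), IMG5_205360 0.79 (SE 0.36) and 1.14 (SE 0.38), IMG5_205160 0.53 (SE 0.33) and 0.88 (SE 0.36), IMG5_201370 0.30 (SE 0.16) and 0.64 (SE 0.20), and IMG5_201230 0.24 (SE 0.25) and 0.57 (SE 0.27).

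After 1 h at 1.5 mg/L no gene passed (0 of 76 with edgeR, 0 of 32 with limma, 2 with DESeq2), and 8 had an unadjusted p under 0.05. The smallest was that of IMG5_201330, at 0.630 ± 0.347 FPKM against 0.139 ± 0.0870 in the controls (log2 2.12, SE 0.52, adjusted p = 0.0511, edgeR), with all 3 exposed libraries above the 4 controls. IMG5_206280 had 46 counts against 4 (log2 3.78, SE 1.23), IMG5_205360 1.24 (SE 0.45) and IMG5_201230 0.95 (SE 0.34). The first was 6.97 without control replicate 4, and the other 2 were 0.69 and 0.63 without replicate 2 of this group. IMG5_201900 had 46 counts against 0, at least 19.9-fold higher by the same floor (counting interval from 15.6), with an adjusted p of 0.163 (fitted log2 7.01, and 5.86 without replicate 2). Each list gave 0 calls over all genes; adjusted over the list alone the cilia list and the kinase list gave 1 each and the others 0. The leishmanolysin-like list had a camera p of 0.864 (down; 0.913 with an estimated correlation), a median of 0.63 and a mean of 0.60. The median over all genes was 0.59, and 5 genes had groups that did not overlap, all upward, where chance gives 2.86% in each direction. A single gene passed without control replicate 1 or without replicate 1 or 2 of this group.

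This group was the most divided. IMG5_201460 measured 0.361 ± 0.198 FPKM, IMG5_205370 0.896 ± 1.15 and IMG5_201630 0.835 ± 0.711, because replicate 2 lay above the other 2 libraries. Across all 14 libraries, control replicates 1, 2 and 3 and replicates 1 and 3 of this group correlated with each other across genes (r 0.46 to 0.70) and inversely with the other 9 libraries (-0.64 to -0.27).

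**Figure D2:**
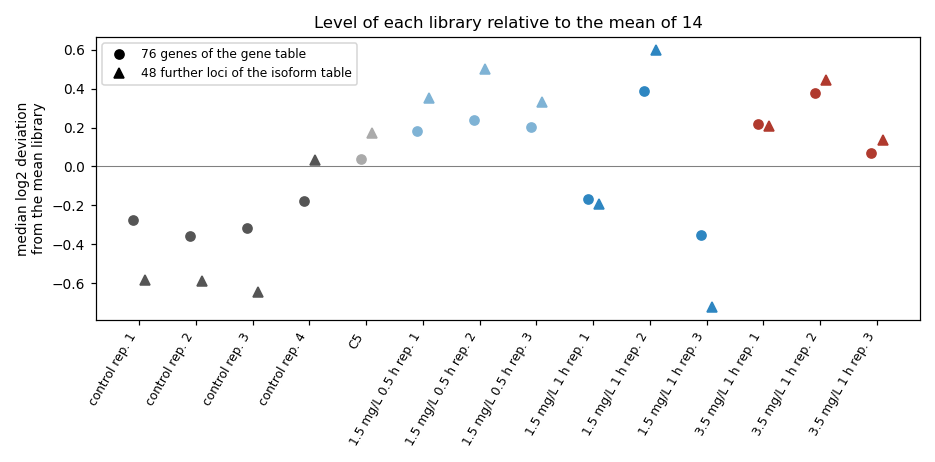
Median log2 deviation of each library from the mean of the 14 (vertical axis), over 76 genes of the gene table (circles) and 48 further loci of the isoform table (triangles). Control replicates 1, 2 and 3 lie at -0.28, -0.36 and -0.32 over the 76 genes, with 1.5 mg/L 1 h replicates 1 and 3 at -0.17 and -0.35; the 7 remaining magnolol libraries lie between 0.07 and 0.39. Control replicate 4 is at -0.18, below 1.5 mg/L 1 h replicate 1, and C5 at 0.036, so the medians over the 76 genes do not separate the 5 libraries from the other 9. Those over the 48 further loci do. There the highest of the 5 was -0.19 (1.5 mg/L 1 h replicate 1) and the lowest of the 9 was 0.031 (control replicate 4).

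The remaining comparisons set the magnolol groups against each other. Between 1 h and 0.5 h at 1.5 mg/L no gene passed (edgeR; 5 with an unadjusted p under 0.05; 0 with limma and 2 with DESeq2). The unnamed genes IMG5_202840 (log2 2.06, SE 0.64) and IMG5_205610 (0 counts at 0.5 h; 1.17 ± 0.814 FPKM at 1 h) had the smallest p. Among named genes the phosphatase IMG5_202650 had -0.67 (SE 0.29) and the calpain-15-like IMG5_202770 -0.96 (SE 0.46). Between 3.5 and 1.5 mg/L at 1 h no gene passed either (edgeR; 3 with an unadjusted p under 0.05; 0 with limma and 1 with DESeq2). IMG5_205990, at 0.592 ± 0.505 FPKM in the lower dose and 0 in the higher, was at least 9.75-fold lower by the floor, with an adjusted p of 0.311. IMG5_201460 had 1.04 (SE 0.52). Every list gave 0 calls in both comparisons. For the leishmanolysin-like list the camera p was 0.908 (up; 0.939 with an estimated correlation) for time and 0.228 (down; 0.437) for dose. The medians over all genes were -0.40 for time and 0.43 for dose. Groups did not overlap in 3 genes upward and 6 downward for time, and in 7 and 4 for dose, where chance gives 5% in each direction. Both counts rose to 17 without replicate 2 of the 1.5 mg/L 1 h group.

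The comparisons with the shared controls were set against each other across the 76 genes, which are not independent replicates. The log2 changes used here were differences of group means of log2(CPM + 0.5), where CPM is the count scaled to library total. They are not the edgeR changes given above, and the offset shrinks changes in genes with few counts. The changes after 0.5 h at 1.5 mg/L and after 1 h at 3.5 mg/L correlated at r = 0.88. Unchanged groups simulated against the same controls gave a mean of 0.43 and an upper limit of their 95% interval of 0.63. The covariance was 0.262 against a simulated 0.0517 (limit 0.0890). With the controls split 2 and 2, r was 0.75 on average. The simulation drew each gene separately and left out the division of the libraries described above. In that division control replicates 1, 2 and 3 lay apart from all libraries of these 2 exposed groups. This alone could raise r, also with split controls, so these values do not tell a response to magnolol from the division. Of the risers, 8 genes were called in both, where independent lists would share 1.66, and IMG5_205990 fell in both. That value leaves out the shared controls. In 100 simulations of unchanged groups against the same controls at most 1 riser was shared, but such groups give few calls, so how much of the overlap the controls add was not settled. For 0.5 h and 1 h at 1.5 mg/L, r was 0.58 (simulated 0.43, limit 0.62; 0.32 with split controls, from 0.048 to 0.62; covariance 0.0876 against 0.0518, limit 0.0864). For both doses at 1 h it was 0.61 (simulated 0.43, limit 0.62; 0.36 with split controls, from 0.081 to 0.66; covariance 0.0950 against 0.0511, limit 0.0859). These 2 correlations thus lay within what the simulated shared controls gave, and their covariances just above it.

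**Figure D3:**
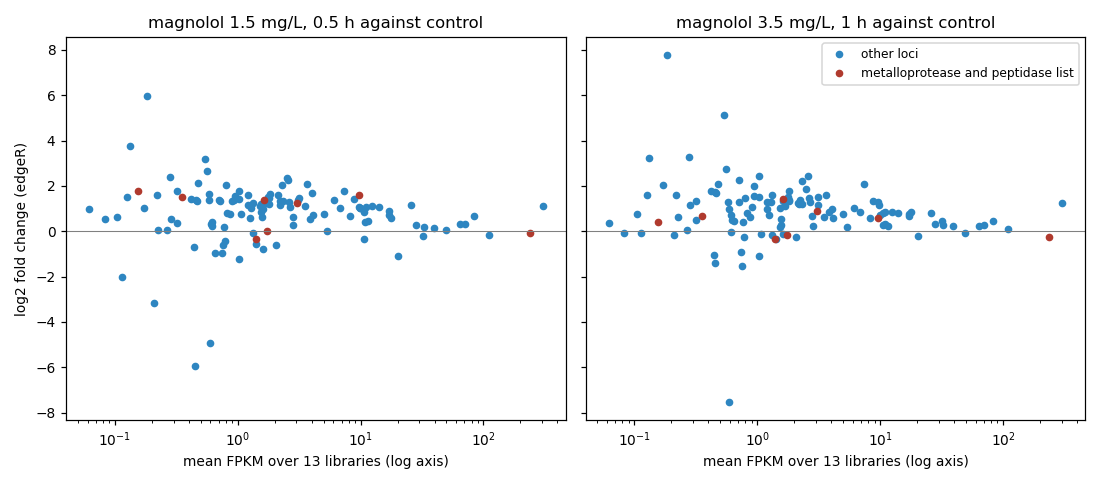
Log2 fold change against control (vertical axis, edgeR) by mean FPKM over 13 libraries (horizontal log axis) of 124 loci from both tables, after 0.5 h at 1.5 mg/L (left) and 1 h at 3.5 mg/L (right); the metalloprotease list is in red. At 3.5 mg/L the 90 loci under 5 FPKM had a median of 1.06 the 18 loci of 5 to 15 FPKM 0.80 and the 16 loci of 15 FPKM or more 0.29.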

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

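The tests of library size, exposure, labels and scaling below were chosen only after the result was seen; those of a constant background and of other splits were written beforehand, except that the shares of tested loci and the increments by level were added afterwards. Chance alone puts about 1 in 20 groups past the limit used for an outlying library, and 5 of 37 named genes passed it among the 4 controls. That share does not apply to 2 of the 5, IMG5_202720 and IMG5_206280, where 3 controls at 0 fix the outcome. Control replicate 4 stood above the other controls in IMG5_201370 (1.36 FPKM against 0.766 to 0.824; gap 0.903 of the range), in the kinase IMG5_203360 (2.38 against 0.325 to 0.666; 0.834) and in IMG5_206280 (0.0514 against 0; 1). Control replicate 1 stood above the others in IMG5_202720 (0.107 FPKM against 0; 1) and IMG5_203540 (1.58 against 0.549 to 0.720; 0.834). The library C5, outside the main comparisons, lay above all 4 controls in 36 of 76 genes and below all 4 in 6, where chance gives 20% each.

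A set of 5 libraries, control replicates 1, 2 and 3 and 1.5 mg/L 1 h replicates 1 and 3, lay apart from the other 9. Library size as the whole cause is argued against: in 19 of 45 pairs across the sets the lower total was in the set of 5. By their labels 4 libraries lay on the other side of the split than their exposure. If the labels are right, this argues against exposure alone. After an exchange of labels between those 1.5 mg/L 1 h libraries and control replicate 4 and C5 none would lie there, so exposure alone stays open. Such an exchange cannot be told apart from other causes: 1 of the 2 untreated libraries matched replicate 2 best among the 7 magnolol libraries of its set. This test was redefined after a first version had been seen. That version took the best match among all 8 other libraries of the set, and 0 of 2 met it because control replicate 4 and C5 matched each other best (r = 0.489), which an exchange would also give. Among the untreated libraries the split follows the description stems (1 stem for control replicates 1, 2 and 3, others for control replicate 4 and C5); the descriptions do not divide the 1.5 mg/L 1 h group, and what the stems stand for is not given, so this stays open and no biological explanation other than exposure was tested.

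Weakly expressed loci were higher after 0.5 h at 1.5 mg/L and 1 h at 3.5 mg/L (median log2 change of 90 loci under 5 FPKM 1.18 and 1.06), but so were the 18 loci of 5 to 15 FPKM (1.03 and 0.80), and across loci level and change correlated at a Spearman coefficient of only -0.14 and -0.15. One scaling factor per library as the whole cause would move abundant loci alike, but the 16 loci of 15 FPKM or more, on which this contrast largely rests, lay lower than the weak loci by 0.89 (permutation p = 0.00739 over loci) and 0.77 (permutation p = 0.00743). All 34 loci of 5 FPKM or more lay lower by 0.48 (permutation p = 0.0198) and 0.43 (permutation p = 0.0357). A constant background as the whole cause would give every locus the same increment and is argued against: of 113 loci under 5 FPKM 26.5% and 25.7% had an upper 95% limit below the median increment (of the 90 tested only 9 and 8, or 22.2% and 18.9% against their own median), and in the 45 tested loci with the higher control level the median increment exceeded that of the other 45 by 0.964 FPKM at 0.5 h (permutation p = 1e-05, the smallest the permutations can give) and by 1.01 FPKM at 3.5 mg/L (permutation p = 2e-05). A dependence on level was also seen after 1 h at 1.5 mg/L. There the medians were 0.63 under 5 FPKM, 0.44 at 5 to 15 FPKM and 0.29 at 15 FPKM or more (Spearman coefficient -0.16). In that comparison the weak loci exceeded the 16 most abundant loci by 0.33 (permutation p = 0.0604) and all 34 loci of 5 FPKM or more by 0.28 (permutation p = 0.0298).

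Exposure to magnolol and the division of the controls both stay open: in the comparison with 0.5 h, 2 of 35 splits of the 7 libraries gave as many genes as the real 10, the highest other giving 23, and at 3.5 mg/L 2 of 35 gave as many as the real 15, the highest other 23. In both cases that other split was control replicates 1, 2 and 3 against the rest, as their shared description stem also divides them, which points to a structure of the samples, and chance could not be excluded. With these 3 summed into 1 sample, 0 genes passed in each comparison with control (edgeR; 10, 3 and 14 with an unadjusted p under 0.05 at 0.5 h, 1.5 mg/L 1 h and 3.5 mg/L).

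For 1.5 mg/L 1 h, all 35 splits gave at least the real count of 0, the highest 18. For 1 h against 0.5 h and for 3.5 against 1.5 mg/L, all 10 splits gave 0 genes, the real one and the highest other alike, and 10 splits are too few for a share under 0.05.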

How the results depend on the processing

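The scaling reported was itself settled after other scalings had been seen. DESeq2, TMM and RLE factors, the filter at a mean of 1 FPKM, the added loci and the fits without libraries in doubt were chosen after seeing the data; limma with a pseudocount of 1 was the test written beforehand. The filter at a mean of 5 FPKM left too few genes and was not run. Counts of genes past the threshold are given as 0.5 h at 1.5 mg/L (10), 1 h at 3.5 mg/L (15), with the other comparisons (each 0) where they moved; unless a cause follows from fewer genes or libraries, the cause was not tested. Scaling that removes part or most of a table-wide shift left no rise past the threshold in these comparisons, except 4 at 3.5 mg/L with quantile normalization. Counts were 0 and 1 with each library centred on its median, which removed only part of the shift. They were 1 and 1 with FPKM rescaled to the same total and 1 and 1 with TMM. RLE gave 1 and 2 (1 gene also for 1 h against 0.5 h), and quantile normalization 4 and 8. All of these scalings were computed from the genes tested alone. Robust estimates with no trend gave 2 and 4. Larger counts came from library quality weights (22 and 23, and 16 in each comparison between magnolol groups), only the groups compared (27 and 28), DESeq2 (22 and 28; 2 for 1.5 mg/L 1 h, 2 for time, 1 for dose) and no filter (18 at 0.5 h, 2 for 1.5 mg/L 1 h). limma gave 16 at 0.5 h with a pseudocount of 0.1 and 16 with a pseudocount of 1. The isoform table gave 0 and 5, with 1 for 1.5 mg/L 1 h; adding its loci gave 7 at 3.5 mg/L.

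The controls decided much. Control replicates 1, 2 and 3, whose descriptions share a stem, summed into 1 sample gave 0 genes in every comparison. C5 among the controls gave 2 and 5, with 1 for 1.5 mg/L 1 h, and C1, C2 and C3 alone gave 26 and 27. Without the 5 libraries set apart, C5 among the controls, 2 and 3 genes passed. With replicate 2 alone at 1.5 mg/L 1 h the counts were 27, 31 and, for that group, 22; this library was chosen because it lay above the other 2, so this upward count follows from the choice and tests nothing. A replicate block, in which control replicate 4 stands alone, gave 29 and 27, and 0 for time, as did a block with only those groups. Leaving out 1 library at a time gave 0 to 27 genes at 0.5 h, 0 to 29 at 3.5 mg/L, 0 to 1 for 1.5 mg/L 1 h, and 0 to 17 for time and for dose.

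The metalloprotease list passed in no comparison as reported, and its direction turned at 0.5 h with C1 to C3 (camera 0.976) and the replicate block (0.905). At 1.5 mg/L 1 h it turned with no filter (0.933), C1 to C3 (0.854), the block (0.789), the isoform table (0.572), the added loci (0.592), the 5 libraries left out (0.563), and replicate 2 alone (0.435). For time the block (0.956) and the 3 controls summed (0.967) turned it. fry, which tests the list against no change and not against the other genes, gave up at 0.5 h (0.119), at 1.5 mg/L 1 h (0.294) and at 3.5 mg/L (0.331), and down for time (0.627). With the preset correlation, and in brackets second with an estimated one, the list passed for dose with the isoform table (0.0134, 0.201), the added loci (0.0139, 0.231), the 5 libraries left out (0.000225, 0.0107) and replicate 2 alone (0.000736, 0.0169), and without the 5 libraries also at 3.5 mg/L (0.00413, 0.0292) and for time (0.0467, 0.0928), and with the 3 controls summed at 3.5 mg/L (0.0411, 0.286). Without the 5 libraries, as with replicate 2 alone, 1.5 mg/L 1 h is the single library that lay high, assumed to vary like the others, so its dose and time values carry no support. With 1 library left out p ran from 0.651 to 0.998 at 0.5 h, 0.414 to 0.982 at 1.5 mg/L 1 h, 0.123 to 0.525 at 3.5 mg/L, 0.386 to 0.999 for time and 0.00607 (0.0749 estimated) to 0.476 for dose. The direction turned in 4 of these 13 fits at 0.5 h, in 2 at 1.5 mg/L 1 h and in 5 for time, and in 0 at 3.5 mg/L and for dose.

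Of 403 values of the 21 named results past the threshold, 235 kept their call, 168 lost it and 0 changed sign; with 1 library left out, 156 of 273 kept it. Of the 40 others, 47 of 738 values gained a call (21 of 520 with 1 library left out) and 12 changed sign: IMG5_205960 at 3.5 mg/L (-0.12 rescaled to the same total, -0.17 with TMM, -0.30 with RLE, -0.089 without the 5 libraries), IMG5_206040 (0.15) and IMG5_206010 (0.068) without the 5 libraries, IMG5_202170 (-0.00093) and, for dose, IMG5_202650 (-0.073) with RLE, and without the 5 libraries or with replicate 2 alone IMG5_201370 for time (0.035 in both) and IMG5_201260 for dose (-0.047 in both). IMG5_206010 also did so without control replicate 1 (0.014). Depth limits the weakest genes: 76 of 99 had counts enough to be tested.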

Other observations

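The tests in this part were chosen after the results were seen. The isoform table added abundant loci, whose transcripts were summed per locus and tested together with the gene table (124 loci, edgeR). The leishmanolysin-like gene IMG5_206020 was far more abundant than its relatives in the gene table, at 238 ± 17.7 FPKM (SD, n = 4) in controls, 224 ± 108 after 0.5 h, 291 ± 120 after 1 h at 1.5 mg/L and 203 ± 41.9 at 3.5 mg/L (n = 3 each; log2 -0.086, 0.29 and -0.23, SE 0.35, 0.34 and 0.35). IMG5_205840 of the same family measured 4.44 ± 3.25, 13.4 ± 2.49, 15.7 ± 19.1 (3.87 to 37.8) and 6.73 ± 0.736 FPKM in the same order, and did not pass either (log2 1.59, 1.82 and 0.60). The asparaginyl endopeptidase IMG5_205770, a lysosomal type of cysteine protease, measured 182 ± 125 FPKM in controls, 388 ± 132 after 0.5 h, 257 ± 220 after 1 h at 1.5 mg/L and 433 ± 124 at 3.5 mg/L (log2 1.25, SE 0.53, adjusted p = 0.124). The Rab-6A-like gene IMG5_204440, of Golgi traffic, stood at 48.9 ± 2.84 FPKM in controls, 50.1 ± 4.65 after 0.5 h, 51.7 ± 1.94 after 1 h at 1.5 mg/L and 46.1 ± 3.97 at 3.5 mg/L. A second gene named after the cation ATPase 13A2, IMG5_205740, measured 56.7 ± 3.23 in controls and 66.6 ± 5.46 at 3.5 mg/L (log2 0.23, SE 0.21), where IMG5_205370 had risen 5.41-fold. The difference between these 2 genes was not tested.

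Of the 48 added loci tested, 3 rose after 0.5 h, all without an annotated gene: MSTRG.30 (2.47 ± 0.584 to 8.40 ± 2.61 FPKM), MSTRG.20 (7.84 ± 1.50 to 16.8 ± 3.22) and MSTRG.31 (6.84 ± 1.57 to 14.3 ± 2.70). MSTRG.30 also rose at 3.5 mg/L (to 10.6 ± 6.30 FPKM, log2 2.09, SE 0.44, adjusted p = 0.0325, edgeR). With these loci included, 8 of 124 loci passed after 0.5 h and 7 at 3.5 mg/L.

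Transcript models of one locus differed widely between libraries. At IMG5_204750 model MSTRG.34.2 had 0 counts in control replicate 4, where MSTRG.34.1 had 1348, and 1137 or more in the other 13 libraries. A candidate explanation is that shared reads were assigned to one or the other model. The coefficient of variation of the locus sum was 13.8%, against 31.2% for its main model, and at IMG5_205750, a proteasome subunit, 22.8% against 46.5%. Sums per locus are therefore the steadier measure for these 2 loci.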
